A study of Arabidopsis thaliana with 12 samples.

How the data were processed

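RNA from whole shoots of 2-week-old Arabidopsis thaliana plants, grown per the labels at 22 °C, 50% humidity and 100 µmol of constant light, was profiled in 12 libraries of 4 genotypes. The values used were whole-number counts per gene as deposited by the authors, with no normalization, per the column values and the labels. The submitters' processing notes name STAR, edgeR and the genome build TAIR10, with no versions and no order. The settings of alignment and counting, the annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes could therefore have been split or dropped, and such genes are reported as uncertain. A 3′ assay counts a transcript near its end, so gene length has little weight, and a lesion upstream of the tag can leave the count in place.

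Libraries were assigned to genotypes from the labels. The third pad4 column carries a number that no pad4 title has, and whether it is the sample titled 4 is not stated. That library was therefore placed in its group with no number of its own and is called pad4 replicate 3. The table held 33331 genes, of which 11272 had 0 counts in every library. Gene names came from a RefSeq gene table of assembly TAIR10.1, which matched 28932 identifiers. The other 4399 identifiers held 0.04 to 0.1% of the counts of a library and kept their codes. The builds differ, so no coordinates are given. No plastid or mitochondrial identifiers were present in the table, and the share of organelle RNA was not analysed here.

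Total counts ranged from 584342 to 10697612, and the 10 most abundant genes took 13.5 to 21% of them. A floor of 3 counts over the group stood for 0.465 CPM in aig2abc, 0.118 CPM in Col-0 and 0.103 CPM in pad4. Replicates of each group differed by more than counting noise, with a chi-square per gene of 3.61 to 64.1, so every library was counted on its own.

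The counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr by group, 15082 in all, were scaled by TMM and tested with the robust quasi-likelihood F-test, two-sided, in a fit of the 4 group means over all 12 libraries. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05 and no fold minimum. The common biological coefficient of variation was 28.7%. The 6 comparisons were aig2abc against Col-0, aig2abc pad4 against pad4, pad4 against Col-0, aig2abc pad4 against aig2abc, aig2abc pad4 against Col-0 and the interaction. Log2 fold changes are given with their standard errors, and levels as CPM with the SD of 3 libraries.

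Gene lists, tests, most other settings and the rule for named genes were fixed before the data were examined. There were 16 lists with 286 members, all in the table, and 6 lists of markers of tissues and cell types. List tests used camera from limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and fry, adjusted over the 96 tests of lists and comparisons. The cell-type lists were adjusted apart. The median, mean and test of a list differed in sign for 8 list results, 0 of them called. With genes without counts in a group at their bound, the median of salicylic acid genes in aig2abc pad4 against pad4 was 1.37 in place of 1.45, and that of defensins in pad4 against Col-0 was -0.53 in place of -0.67. Named genes were AIG2A, AIG2B, AIG2C and PAD4, a panel of defence genes, up to 4 called members per list and comparison with the smallest p, and the 6 largest changes per direction. The last needed a mean log2 CPM of at least 1 and, outside the interaction, no overlap between replicates. Members named beside small counts that this rule does not take, such as GGT1, SUR1, LTI30, ADR1-L2, PDIL1-2, PR3 and the cell-type markers, were chosen after their values were seen.

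The fits were tested on simulated counts with known changes, drawn from the means and library sizes of the real data. For aig2abc against Col-0, 5 of 100 genes changed 2-fold and 59 of 100 changed 4-fold were recovered among 14758 genes, with 2 false calls. For aig2abc pad4 against pad4 these were 15 and 78 of 100, with 6 false calls. The list test called 5 of 5 raised lists and 0 of the others among 20 lists in aig2abc pad4 against pad4, over 14761 genes. In these simulations small changes were often missed, more so in the comparison with the shallow aig2abc libraries. Far fewer genes changed there than were called in the real aig2abc fit, and no replicate axis was simulated, so these rates need not hold for the real data. There 4797 of 5656 calls in aig2abc against Col-0 were changes of 2-fold or more, and 578 of 603 in aig2abc pad4 against pad4.

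Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fold minimum of 2, fits of only the groups compared, the replicate number as a block, and leaving out each library. A further 5 were chosen after seeing the data. The replicate axis was the leading axis of differences within groups of log2 CPM over the 9 libraries outside aig2abc, with a prior count of 2, and the score of each library on it was used as a covariate, and again together with an estimated correlation in the list tests. In another, every library was thinned at random to the smallest total, 584342 counts. The others left out aig2abc replicate 2 with the rest thinned to aig2abc replicate 1, and left out Col-0 replicate 1 together with aig2abc pad4 replicate 3. As a test of depth, also chosen after seeing the data, only the aig2abc pad4 libraries were thinned, to the totals of the aig2abc libraries. In simulated data for aig2abc against Col-0 with such an axis (14738 genes), 141 of 200 changed genes and 185 of 3000 axis genes were called without the covariate, 88 and 12 with it, and 80 and 774 with scores exchanged at random within groups. A fit without organelle genes had nothing to remove and was not run.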

Results

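Transcripts were counted by 3′ RNA-seq, which reads the 3′ ends of mRNAs, in whole shoots of 2-week-old Arabidopsis thaliana plants of 4 genotypes, with 3 libraries each. The genotypes were the wild type Col-0, a mutant labelled aig2abc for the neighbouring genes AIG2A, AIG2B and AIG2C, a mutant of PAD4, and the combination of both, called aig2abc pad4 here. PAD4 encodes a lipase-like protein that promotes salicylic acid signalling in plant immunity. The study asks whether the AIG2 genes hold back chemical defence, and the PAD4 mutation tests how far the aig2abc response runs through that regulator. The labels do not state whether the libraries of a genotype came from separately grown plants, so the p-values measure only the spread between these libraries, which may be technical.

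The total counts were 9026738, 6561011 and 9742035 in the Col-0 libraries, 10298550, 10697612 and 7991739 in pad4 and 8330632, 5542138 and 6429050 in aig2abc pad4. The aig2abc libraries were shallower, at 2867679, 584342 and 3005199 counts, and aig2abc replicate 2 detected 12980 genes where the most complete library detected 19426. The 9 libraries outside aig2abc also differed among replicates along a shared axis, which held 52.5% of their variance within groups. On this replicate axis the Col-0 libraries scored 84, 11.9 and 8.06, the pad4 libraries 52.9, 8.1 and -12.6 and the aig2abc pad4 libraries 57.6, 47.4 and -39.4. All 3 aig2abc libraries scored lower than these, at -73.7, -83.5 and -60.8.

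**Figure D1:**
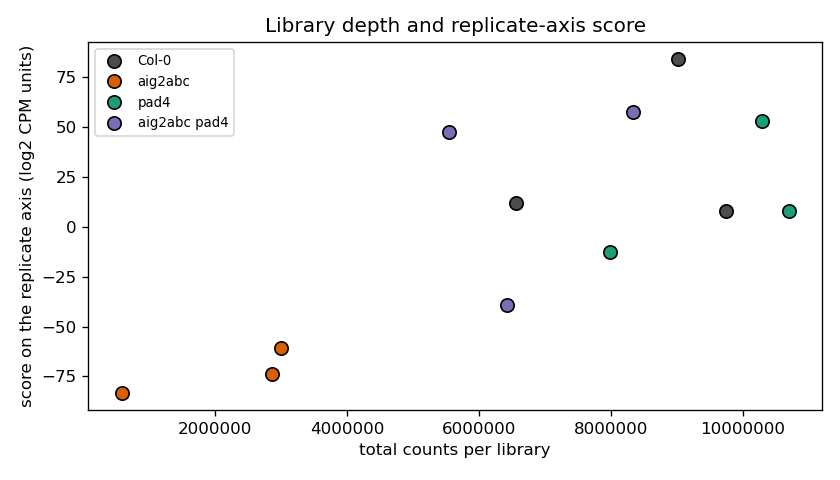
Score of each of the 12 libraries on the replicate axis (vertical, log2 CPM units) against its total counts (horizontal), with 1 point per library, coloured by genotype. The aig2abc libraries lie apart on both scales, at 3005199 counts or fewer and scores of -60.8 or lower.

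The targeted genes were examined in every library first. AIG2C, the third gene of the cluster, was nearly silent in both groups that carry aig2abc. It had 4, 0 and 4 counts in the aig2abc libraries and 5, 2 and 2 in aig2abc pad4, against 45.5 ± 16.5 CPM (counts scaled to library size; SD, n = 3) in Col-0 and 39 ± 5.48 CPM in pad4. PAD4 stood at 2.68, 3.45 and 2.93 CPM in the pad4 libraries and at 5.1, 8.14 and 5.92 CPM in aig2abc pad4. In Col-0 it was at 17.1, 27.2 and 35.2 CPM, and in aig2abc at 56.7, 42.5 and 51.2 CPM. AIG2A transcripts were still counted in the mutants, at 109, 77.2 and 85 CPM in the aig2abc libraries against 73.2, 64.3 and 62.6 CPM in Col-0. In aig2abc pad4 they stood at 209, 227 and 209 CPM against 50.5, 50.2 and 46.8 CPM in pad4. AIG2B was at 575, 838 and 714 CPM in aig2abc and at 500, 844 and 963 CPM in Col-0. It was at 84.5, 125 and 353 CPM in aig2abc pad4 and at 579, 1130 and 1260 CPM in pad4. A 3′ tag outside the altered part of a gene checks nothing, and the labels do not describe the AIG2A and AIG2B lesions, so only AIG2C and PAD4 bear on the genotypes. AIG2A, AIG2B and AIG2C are related copies that can share reads, which makes the split between them uncertain.

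**Figure D2:**
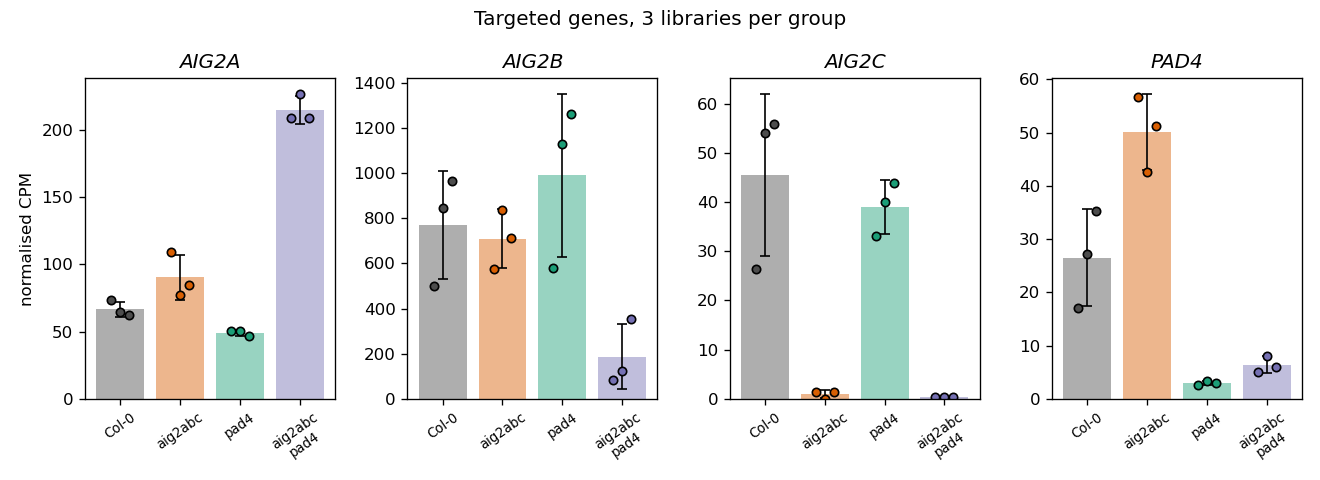
Level of AIG2A, AIG2B, AIG2C and PAD4 (vertical, normalised CPM, a scale of its own for each gene) by genotype (horizontal), with points for libraries, bars for the group mean and whiskers for the SD (n = 3). AIG2C lies at 1.48 CPM or lower in every aig2abc and aig2abc pad4 library, while AIG2B in aig2abc stays between 575 and 838 CPM.

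The first comparison set aig2abc against Col-0, to find what the AIG2 mutations change in plants with PAD4. Genes for defensins, camalexin synthesis and glutathione transferases rose in aig2abc. Of the photosynthesis genes 15 of 26 fell, and of the abscisic acid and cold response genes 6 of 12, list calls that did not pass with an estimated correlation (adjusted p = 0.0977 and 0.158). PDF1.2A, a defensin induced by jasmonate and ethylene, rose from 8.98 ± 3.53 to 752 ± 158 CPM (SD, n = 3 each), a log2 change of 6.40 ± 0.41 (SE). CYP71A13, an enzyme on the way to camalexin, rose from 2.25 ± 0.919 to 86.9 ± 11.9 CPM, and PAD3, which completes camalexin, from 0.638 ± 0.26 to 8.25 ± 0.577 CPM. LHCB5, an antenna protein of photosystem II, fell from 2220 ± 694 to 297 ± 39.9 CPM. Of 15082 genes tested, 2709 were higher and 2947 lower in aig2abc by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These numbers were 2679 and 2101 with limma-voom, 2258 and 3313 with no filter on low counts, and 1657 and 2073 without aig2abc replicate 1.

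Of the 11 tested genes for ethylene and jasmonate defensins and their regulators, 9 rose and 9 rose when adjusted over the list alone (camera adjusted p = 4.2e-17). They included ORA59, the ERF activator of defensin genes, up by 3.98 ± 0.31 on the log2 scale, and ERF2, up by 2.94 ± 0.26. PDF1.2A, PDF1.2B, PDF1.2C and PDF1.3 are close copies that can share reads, as can CYP71A12 and CYP71A13, so their separate values are uncertain. On the camalexin list 7 of 9 genes rose and GGT1 fell by 2.45 ± 0.70, with 7 and 1 adjusted over the list alone (camera adjusted p = 4e-08). AAO1, an aldehyde oxidase, rose by 4.35 ± 0.45 and the glutathione transferase GSTU4 by 3.41 ± 0.33. Of the 14 glutathione transferases and other detoxification genes, 10 rose, and 10 adjusted over the list alone (camera adjusted p = 1.1e-06). GSTF2 rose from 578 ± 166 to 7140 ± 147 CPM. In tryptophan synthesis 7 of 14 genes rose, and 7 adjusted over the list alone (camera adjusted p = 0.00122), among them TSA1, the tryptophan synthase alpha subunit, by 2.22 ± 0.25 and the anthranilate synthase subunit ASB1 by 1.87 ± 0.29. These 4 calls also passed with an estimated correlation, at adjusted p = 0.004, 0.00674, 0.00489 and 0.026.

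Among salicylic acid genes 13 of 27 rose and 14 adjusted over the list alone (camera adjusted p = 3.61e-05; adjusted p = 0.201 with an estimated correlation). ICS1, the isochorismate synthase that makes the salicylic acid precursor, rose by 2.43 ± 0.35 and the transcription factor WRKY53 by 2.49 ± 0.42. PR1, the classic marker gene of salicylic acid responses, rose from 155 ± 63.7 to 322 ± 59.8 CPM, a log2 change of 1.06 ± 0.33 (edgeR adjusted p = 0.0175). That call was lost when Col-0 replicate 1 or 2, or aig2abc replicate 1 or 3, was left out, with the highest adjusted p at 0.105 without aig2abc replicate 1, and also with the replicate-axis covariate, at 0.0543 and a log2 change of 1.33 ± 0.43. PR2 and PR5 did not pass, at 0.85 ± 0.34 and 0.48 ± 0.36. Both passed without Col-0 replicate 3 (edgeR adjusted p = 0.00133 and 0.0152), as did PR2 without aig2abc pad4 replicate 3 (0.0417). Of the 22 indole glucosinolate genes 10 rose, while CYP79B3 and SUR1 fell by 2.07 ± 0.49 and 1.03 ± 0.35. Adjusted over the list alone, 12 rose and 2 fell (camera adjusted p = 0.000159; adjusted p = 0.1 with an estimated correlation). MYB51, an activator of this pathway, rose by 3.48 ± 0.37 and the indole glucosinolate methyltransferase IGMT2 by 2.33 ± 0.39. Of the 8 senescence genes 7 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00033; adjusted p = 0.0817 with an estimated correlation), with SAG13 up by 2.47 ± 0.33.

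Photosynthesis genes encoded in the nucleus fell for 15 of 26 members and rose for 0, with 16 lower adjusted over the list alone (camera adjusted p = 1.48e-07; adjusted p = 0.0977 with an estimated correlation). The light-harvesting gene LHCB1.3 fell by 2.46 ± 0.31 and GAPB, of the Calvin cycle, by 1.84 ± 0.25. Of the 12 abscisic acid and cold response genes 6 fell and LTI30 rose by 1.00 ± 0.37, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.158 with an estimated correlation). COR15A, a cold-induced protein of chloroplasts, fell by 3.35 ± 0.38 and KIN2 by 2.34 ± 0.29.

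A further 4 lists were called at camera adjusted p of 0.0207 to 0.0447, and the counts adjusted over the list alone equalled those over all genes unless given. Of 21 immune receptor and early signalling genes 6 rose, including RIN4, a guarded immune regulator, by 2.52 ± 0.36, and ADR1-L2 fell by 2.62 ± 0.98 (camera adjusted p = 0.0312; adjusted p = 0.204 with an estimated correlation). Of 14 cysteine-rich receptor-like kinases 5 rose, and CRK21 fell by 1.84 ± 0.53, a call lost without aig2abc replicate 1 at adjusted p = 0.0772 by edgeR and at -2.60 without aig2abc replicate 3 (camera adjusted p = 0.0447; adjusted p = 0.327 with an estimated correlation). The call of this list was lost without aig2abc replicate 3 (camera adjusted p = 0.0814), aig2abc pad4 replicate 3 (0.0668) or pad4 replicate 1 (0.0523). Of 15 genes for protein folding in the endoplasmic reticulum 7 rose, such as the chaperone helper ERDJ3B by 1.89 ± 0.29, and PDIL1-2 fell by 3.04 ± 1.16, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0207; adjusted p = 0.213 with an estimated correlation). The folding list was not called without Col-0 replicate 2 (camera adjusted p = 0.065). Of 4 heat shock genes HSP70 rose by 1.70 ± 0.37 and HSP90.1 by 3.68 ± 0.54, the latter by 4.59 without Col-0 replicate 3 (camera adjusted p = 0.0447; adjusted p = 0.167 with an estimated correlation). The remaining 3 lists were not called. Jasmonate genes had 7 of 14 higher, such as JAZ1 at 2.08 ± 0.37, and the synthesis genes LOX2 and AOS lower at -1.54 ± 0.41 and -1.27 ± 0.30 (camera adjusted p = 0.0605). They were called without aig2abc replicate 1 (camera adjusted p = 0.0338) or Col-0 replicate 1 (0.0464) or 2 (0.0351). Aliphatic glucosinolate genes had 3 higher and 11 lower of 25, with 12 lower adjusted over the list alone (camera adjusted p = 0.229). The relatives of AIG1 and AIG2 had 2 higher, AIG1 at 2.47 ± 0.47 and GGCT2;2 at 3.18 ± 0.59, and 2 lower of 10, AIG2C and GGCT2;3, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.542). The GGCT2;3 call, at -0.88 ± 0.31, was lost in 4 omissions, with edgeR adjusted p up to 0.118 without Col-0 replicate 2.

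Among the largest rises, MRD1 went from 2 ± 0.411 to 492 ± 81.3 CPM, and the defensin-like LCR67, with 0 counts in Col-0, was at least 51-fold higher. RBK1, a receptor-like cytoplasmic kinase with 2 counts in Col-0, was higher by a ratio of 145 with a 95% counting interval of 38.8 to 1220. Fitted values ranked genes with 0 counts in the shallow aig2abc libraries as the largest falls, but such values are no bounds. Falls among genes with counts there, given as examples and not as a ranking, included log2 changes of -7.21 for AT3G01345, -5.24 for AT3G42658.1 and -5.15, a 35.6-fold fall, for AIG2C. AT3G01345, AT3G42658.1 and AIG2C had 4, 11 and 8 counts over the aig2abc libraries, so these values rest on counts near the floor. The genes with 0 counts were bounded only at lower folds, such as AT5G41920, at least 23.4-fold lower, and AT1G68730, at least 15-fold lower. These bounds use a floor of 3 counts over the group, and such intervals and floors cover counting error only. With the replicate-axis score as a covariate 1377 genes were called, 1168 of them from the 5656, while scores exchanged at random within groups gave 193 to 5280 calls in 20 exchanges. The median absolute log2 change of the 5656 was 1.57 without a covariate, 0.816 with the real scores and 0.877 to 2 with exchanged ones. At the preset correlation, 10 of the 11 lists called up were still called up with the covariate, all but heat shock (adjusted p = 0.0614), and photosynthesis genes were still down (adjusted p = 1.97e-16). With an estimated correlation only 4 of these 11 lists passed without the covariate and 5 with it, and photosynthesis did not pass with the covariate either (adjusted p = 0.0829). In other fits 2769 genes were called with all libraries thinned to the smallest total, and 3730 without aig2abc replicate 1.

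The second comparison set aig2abc pad4 against pad4, to find what the same mutations change without PAD4, and it shares no library with the first. Defensin, camalexin and detoxification genes rose here too, and PR1, PR2 and PR5 rose as well. PDF1.2A went from 6.83 ± 2.27 to 3670 ± 846 CPM (SD, n = 3 each), a log2 change of 9.06 ± 0.45. CYP71A13 went from 0.605 ± 0.358 to 64.2 ± 5.52 CPM. PR1 went from 4.86 ± 1.17 to 219 ± 72 CPM, a log2 change of 5.49 ± 0.40 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.76e-08). By the same test 503 genes were higher and 100 lower. These numbers were 960 and 757 with the replicate-axis covariate, 618 and 317 without aig2abc pad4 replicate 3, and 359 and 22 without aig2abc pad4 replicate 2.

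On the defensin list 10 of 11 genes rose, and 11 adjusted over the list alone (camera adjusted p = 2.56e-65), with ORA59 up by 4.53 ± 0.31. PDF1.2B, with 0 counts in pad4, was at least 396-fold higher. On the camalexin list 8 of 9 genes rose, and 8 adjusted over the list alone (camera adjusted p = 5.1e-35). PAD3, with 2 counts in pad4, was higher by a ratio of 186 (95% counting interval 50.9 to 1540), and its fitted log2 change was 9.23 without pad4 replicate 3 against 6.95 with it. Both counts lay in that library, so the value of 9.23 was fitted against pad4 libraries without counts and is no bound. GSTU4 rose by 5.11 ± 0.36 on the log2 scale. Detoxification genes rose for 9 of 14, and for 11 adjusted over the list alone (camera adjusted p = 5.27e-21), among them GSTF6 by 4.25 ± 0.42 and GSTF2 by 2.90 ± 0.33. In tryptophan synthesis 6 of 14 rose, and 8 adjusted over the list alone (camera adjusted p = 2.09e-06), such as IGPS by 1.92 ± 0.27 and TSA1 by 1.90 ± 0.25. Indole glucosinolate genes rose for 11 of 22, and for 14 adjusted over the list alone (camera adjusted p = 1.97e-16), with MYB51 up by 2.73 ± 0.36 and IGMT2 by 3.47 ± 0.38. Without pad4 replicate 3 the IGMT2 value was 4.07.

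Salicylic acid genes rose for 14 of 27, and for 19 adjusted over the list alone (camera adjusted p = 2.56e-25). PR5, a thaumatin-like protein, rose by 3.17 ± 0.39 and the glucanase gene PR2 by 2.63 ± 0.36, whereas ICS1 did not pass, at 0.90 ± 0.35. Senescence genes rose for 5 of 8, and for 8 adjusted over the list alone (camera adjusted p = 3.98e-18), with SAG13 up by 4.39 ± 0.36 and the cysteine protease gene SAG12, at 2 counts in pad4, up by a ratio of 231 (95% counting interval 63.3 to 1910). Cysteine-rich receptor-like kinases rose for 5 of 14, and for 9 adjusted over the list alone (camera adjusted p = 9.34e-08), with CRK6 up by 3.10 ± 0.60, or by 4.43 without pad4 replicate 3. Of the immune receptor and early signalling genes 3 of 21 rose, and 7 adjusted over the list alone (camera adjusted p = 1.81e-07), and NHL10, with 0 counts in pad4, was at least 35.2-fold higher. These 9 lists also passed with an estimated correlation, and 8 of them with the replicate-axis covariate as well.

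The other 6 called lists did not pass with an estimated correlation. Photosynthesis genes had 0 of 26 members called, and 0 adjusted over the list alone, with a median log2 change of -0.54 (camera adjusted p = 2.96e-06; adjusted p = 0.127 with an estimated correlation). Aliphatic glucosinolate genes had 0 of 25 called and 4 lower adjusted over the list alone, with a median of -0.57 (camera adjusted p = 5.53e-05; adjusted p = 0.0781 with an estimated correlation). In the abscisic acid and cold list KIN2 fell by 1.51 ± 0.28 and KIN1 by 1.61 ± 0.42 of 12, with 3 lower adjusted over the list alone (camera adjusted p = 0.0205; adjusted p = 0.17 with an estimated correlation). The KIN1 call was lost in 5 omissions, with the highest edgeR adjusted p at 0.232 without aig2abc pad4 replicate 2. Jasmonate genes rose for 3 of 14, led by the tyrosine aminotransferase TAT3 at 2.18 ± 0.37, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.105 with an estimated correlation). Folding genes of the endoplasmic reticulum had 0 of 15 called and 1 higher adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.165 with an estimated correlation). Of the 4 heat shock genes HSP70 rose by 1.52 ± 0.35, a call lost without pad4 replicate 1 or 3 (edgeR adjusted p up to 0.0655), with 2 higher adjusted over the list alone (camera adjusted p = 0.0353; adjusted p = 0.182 with an estimated correlation). The heat shock list was not called in 8 omissions, with camera adjusted p up to 0.226 without aig2abc pad4 replicate 3. The list of AIG1 and AIG2 relatives was not called (camera adjusted p = 0.38). Within it AIG2A rose by 2.13 ± 0.23, AIG2C fell by 6.59 ± 0.43 and AIG2B fell by 2.40 ± 0.45, the last by -3.24 without aig2abc pad4 replicate 3. Other large rises were Prx37, a peroxidase with 1 count in pad4, by a ratio of 2260 (95% counting interval 405 to 89300), and LCR67, at least 213-fold higher. The fitted log2 change of Prx37 was 10.25, and 11.79 without pad4 replicate 2. That library held the only pad4 count, so the latter value is no bound.

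The genes that rose overlapped between these comparisons of separate libraries. Of the 503 genes higher in aig2abc pad4 than in pad4, 325 were also higher in aig2abc than in Col-0, where independent lists would share 90.3 (odds ratio 9.34, two-sided Fisher's exact test p = 1.78e-123; genes are not independent). Of the 100 lower genes 67 were shared, where 19.5 would be (odds ratio 8.53, Fisher's exact test p = 4.94e-25). Among all 503, 88.3% had the same sign in the first comparison. Counted from the first comparison the shares were lower. Of the 2709 genes higher in aig2abc 12% were called higher in aig2abc pad4 against pad4, 62.8% had the same sign there and their median log2 change was 0.13. Of the 2947 lower genes 2.27% were called lower there, 66.6% had the same sign and the median was -0.18. The count for aig2abc pad4 against pad4 was 1717 with the replicate-axis covariate and 192 with thinned libraries, and the overlap of both directions, 392 genes, was 251 with each comparison fitted alone and 120 with thinned libraries. The count was 381 without pad4 replicate 2 or without aig2abc pad4 replicate 2, and 935 without aig2abc pad4 replicate 3.

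**Figure D3:**
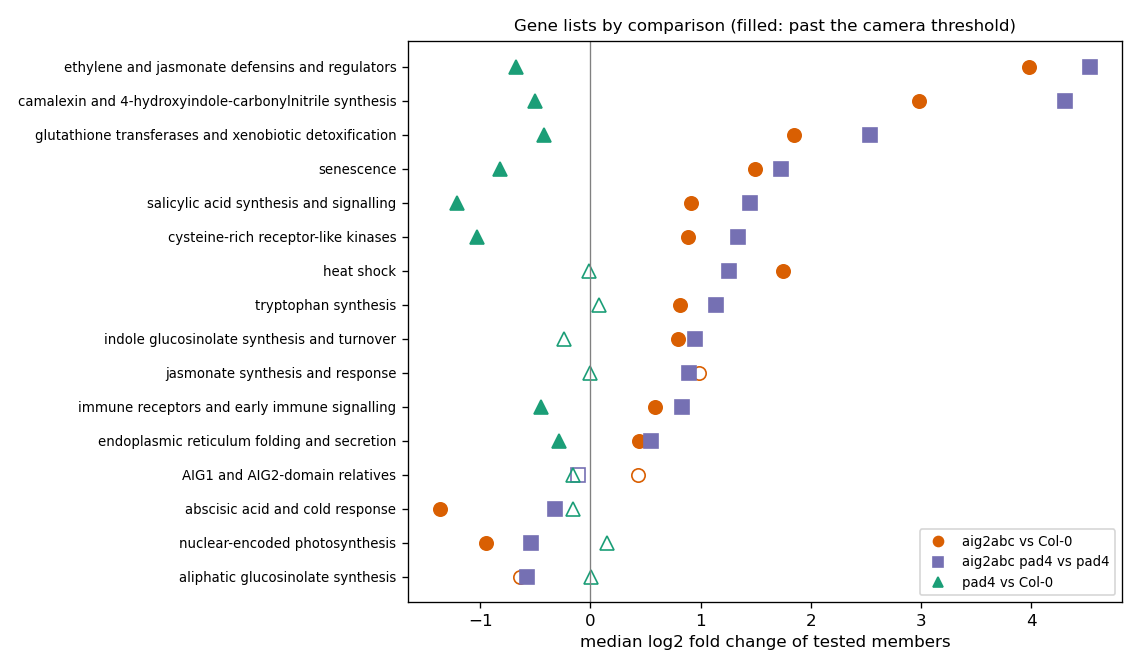
Median log2 fold change of the tested members (horizontal) of the 16 gene lists (vertical) in 3 comparisons, with circles for aig2abc against Col-0, squares for aig2abc pad4 against pad4 and triangles for pad4 against Col-0, filled where camera's adjusted p passed the threshold. Defensin genes stand at medians of 3.98 in aig2abc against Col-0 and 4.53 in aig2abc pad4 against pad4, and salicylic acid genes at -1.21 in pad4 against Col-0.

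The interaction tested whether the aig2abc effect differed between plants without and with PAD4. Positive values mean that a gene rose more, or fell less, in the pad4 background. The lists called were salicylic acid genes with 6 positive of 27, defensins with 4 of 11 and photosynthesis genes with 6 of 26, and none of these calls passed with an estimated correlation (adjusted p = 0.464, 0.16 and 0.413). PR1 differed by 4.43 ± 0.49 on the log2 scale (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000408), since it went from 155 ± 63.7 to 322 ± 59.8 CPM with PAD4 and from 4.86 ± 1.17 to 219 ± 72 CPM without it (SD, n = 3 each). PNP-A, a small secreted natriuretic-like peptide, differed by 3.40 ± 0.55 and S3H, a salicylic acid hydroxylase, by 5.48 ± 0.91. S3H had 2 counts over the pad4 libraries, so its fitted value is uncertain. In all, 1287 genes had a positive and 940 a negative interaction. These numbers were 684 and 899 with limma-voom, 72 and 14 with the replicate-axis covariate, 511 and 218 without aig2abc replicate 1, 323 and 126 without pad4 replicate 3, and 443 and 169 or 340 and 89 without aig2abc pad4 replicate 1 or 2.

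Salicylic acid genes had 6 positive and 1 negative of 27, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.0203; adjusted p = 0.464 with an estimated correlation). That list was not called without Col-0 replicate 3 (camera adjusted p = 0.134). The negative member was ICS1 at -1.53 ± 0.49, a call lost in 9 of 12 omissions, with the highest adjusted p by edgeR at 0.142 without aig2abc pad4 replicate 1. Defensins and regulators had 4 positive of 11, and 5 adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.16 with an estimated correlation). These were PDF1.2A at 2.66 ± 0.48, PDF1.2C at 2.78 ± 0.54, PDF1.3 at 4.64 ± 0.78 and the chitin-binding gene PR4 at 3.12 ± 0.61, which was 2.39 without Col-0 replicate 1. Photosynthesis genes had 6 positive of 26, and 8 adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.413 with an estimated correlation), among them LHCB5 at 2.31 ± 0.45 and LHCB1.3 at 2.31 ± 0.41. The photosynthesis list was not called without Col-0 replicate 2 (camera adjusted p = 0.101), pad4 replicate 1 (0.0575) or 3 (0.0639), or aig2abc pad4 replicate 3 (0.085).

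The other 13 lists were not called, with camera adjusted p between 0.0523 for camalexin synthesis and 0.874 for jasmonate genes. Camalexin synthesis was called in 8 of the omissions, with camera adjusted p down to 0.0182 without pad4 replicate 3. Single members still differed. SAG21 had an interaction of 1.96 ± 0.35, the transferase genes GSTF6 and GSTF10 of 2.66 ± 0.55 and 1.70 ± 0.36, and COR15A of 2.23 ± 0.49. CYP83A1 and SOT17 of aliphatic glucosinolate synthesis had interactions of -1.96 ± 0.42 and -2.43 ± 0.53. AIG2A had 1.68 ± 0.31. AIG2B had -2.28 ± 0.61 (edgeR adjusted p = 0.0272), a call lost in 8 omissions with adjusted p up to 0.0775 without aig2abc pad4 replicate 2, at -3.11 without aig2abc pad4 replicate 3 and -0.65 ± 0.37 with the covariate. Of the 61 named genes called here, 26 stayed called in every omission. With the replicate-axis covariate 86 genes were called, 77 of them from the 2227, and PR1, PNP-A, S3H, PDF1.2A, SAG21, AIG2A and LHCB1.3 were among those still called, while PDF1.2C (1.41 ± 0.48), PDF1.3 (2.17 ± 0.58), PR4 (1.49 ± 0.44), LHCB5 (0.96 ± 0.35), GSTF6 (1.22 ± 0.46), GSTF10 (1.18 ± 0.35), COR15A (1.00 ± 0.36), CYP83A1 (-1.17 ± 0.39) and SOT17 (-0.97 ± 0.35) were not. Scores exchanged at random within groups kept 0 to 90.6% of the 2227 calls in 20 exchanges, and 37% or less in 17 of them. With thinned libraries 1230 genes were called. The count was 946 without Col-0 replicate 1, 729, 602 and 722 without aig2abc replicate 1, 2 or 3, 1075 and 449 without pad4 replicate 2 or 3, and 612, 429 and 4588 without aig2abc pad4 replicate 1, 2 or 3.

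The comparison of pad4 with Col-0 asked what loss of PAD4 alone changes. Salicylic acid genes and cysteine-rich receptor-like kinases fell. PR1 fell from 155 ± 63.7 to 4.86 ± 1.17 CPM (SD, n = 3 each), a log2 change of -4.99 ± 0.39 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.29e-06). PR2 fell by 4.21 ± 0.38 and PR5 by 3.26 ± 0.39, which were -3.56 and -2.62 without Col-0 replicate 3. PNP-A fell by 4.04 ± 0.41. S3H, with 2 counts in pad4, was lower by a ratio of 66.9 (95% counting interval 18.1 to 559). By this test 103 genes were lower and 1, IAGLU, an indole-3-acetate glucosyltransferase gene, was higher, at 1.19 ± 0.22; that call was lost without Col-0 replicate 1 or 2 (adjusted p up to 0.0633). The higher and lower genes numbered 9 and 149 with DESeq2, 23 and 217 with the replicate-axis covariate, 6 and 148 with no filter on low counts, 0 and 72 with these groups fitted alone, and 6 and 126 without aig2abc pad4 replicate 3.

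Salicylic acid genes fell for 7 of 27, and for 17 adjusted over the list alone (camera adjusted p = 1.65e-42), with a median log2 change of -1.21, or -1.19 with genes without counts at their bound. Receptor-like kinases of the cysteine-rich family fell for 5 of 14, and for 8 adjusted over the list alone (camera adjusted p = 2.65e-14), with CRK4 down by 3.11 ± 0.46. Of the senescence genes SAG13 fell by 2.31 ± 0.34 and SAG21 by 1.68 ± 0.25, with 4 of 8 lower adjusted over the list alone (camera adjusted p = 4.52e-07). On the camalexin list GSTU4 fell by 1.61 ± 0.36, a call lost in 10 omissions (edgeR adjusted p up to 0.257 without Col-0 replicate 3), with 4 of 9 lower adjusted over the list alone (camera adjusted p = 0.000119). These 4 calls also passed with an estimated correlation, at adjusted p = 0.00466, 0.00694, 0.00954 and 0.018. Another 4 lists were called lower with no single member called over all genes. Defensins and regulators had 1 of 11 lower adjusted over the list alone (camera adjusted p = 0.000974; adjusted p = 0.148 with an estimated correlation). Immune receptor genes had 3 of 21 lower adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.0977 with an estimated correlation). Folding genes had 3 of 15 lower adjusted over the list alone (camera adjusted p = 0.00276; adjusted p = 0.17 with an estimated correlation), and the list was not called without Col-0 replicate 3 (0.24). Detoxification genes had 1 of 14 lower adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.116 with an estimated correlation), and the list was not called in 10 omissions, with camera adjusted p up to 0.404 without Col-0 replicate 3. The other 8 lists were not called, among them photosynthesis (median log2 change 0.15; camera adjusted p = 0.0802) and tryptophan synthesis (0.08; camera adjusted p = 0.874). Photosynthesis was called without pad4 replicate 3 (camera adjusted p = 0.00161) or Col-0 replicate 2 (0.011), aliphatic glucosinolate synthesis without Col-0 replicate 2 (0.0327), and the AIG1 and AIG2 relatives without Col-0 replicate 1 (0.000904) or pad4 replicate 2 (0.0241) or 3 (0.0222). The number of genes called was 158 with DESeq2, 240 with the replicate-axis covariate, 29 with thinned libraries and 67 without pad4 replicate 3.

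The comparison of aig2abc pad4 with aig2abc asked what loss of PAD4 changes in the aig2abc mutant. Salicylic acid genes fell for 9 of 27 members, photosynthesis genes rose for 11 of 26, and defensin genes rose for 5 of 11 and fell for 2. These list calls did not pass with an estimated correlation (adjusted p = 0.184, 0.17 and 0.212). PAD4 fell by 3.00 ± 0.31 on the log2 scale, PR2 from 371 ± 19.4 to 68.9 ± 5.63 CPM and ICS1 from 77.5 ± 15.5 to 16.8 ± 7.24 CPM (SD, n = 3 each). PR1 did not pass, at -0.56 ± 0.32 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.208). PDF1.2A rose by 2.28 ± 0.33 and LHCB5 by 2.30 ± 0.33. In this test 1924 genes were higher and 1737 lower. These numbers were 1091 and 1805 with limma-voom, 2451 and 1353 with no filter on low counts, and 935 and 488 or 972 and 455 without aig2abc pad4 replicate 1 or 2.

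None of the 6 list calls here passed with an estimated correlation. Salicylic acid genes fell for 9 of 27, and for 9 adjusted over the list alone (camera adjusted p = 4.43e-06; adjusted p = 0.184 with an estimated correlation), with SARD1, an activator of ICS1, down by 2.57 ± 0.40. Photosynthesis genes rose for 11 of 26, and for 12 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.17 with an estimated correlation), with LHCB1.3 up by 1.89 ± 0.30. Defensin genes had 5 higher and 2 lower of 11, PR3 and ERF2, and the same adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.212 with an estimated correlation). Cysteine-rich receptor-like kinases had 4 lower, such as CRK4 at -1.97 ± 0.43, and CRK21 higher of 14, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.213 with an estimated correlation). The AIG1 and AIG2 relatives had 3 lower of 10, AIG1 at -3.46 ± 0.50, GGCT2;2 at -2.77 ± 0.58 and AIG2B at -1.92 ± 0.44, and AIG2A higher at 1.24 ± 0.22, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.213 with an estimated correlation). Without aig2abc pad4 replicate 3 GGCT2;2 was at -3.80 and AIG2B at -2.75, and without aig2abc pad4 replicate 2 the calls of CNX1 and CRT1A were lost (edgeR adjusted p = 0.0655 and 0.0559), the former also without aig2abc pad4 replicate 1 (0.0649). Folding genes had 3 lower of 15, CNX1, CRT1A and ERDJ3B, the last at -1.72 ± 0.29, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0262; adjusted p = 0.266 with an estimated correlation). The kinase and folding lists were not called without aig2abc pad4 replicate 3 (camera adjusted p = 0.15 and 0.103), nor the defensin list without aig2abc replicate 2 (0.0673). Camalexin synthesis was among the 10 lists not called (camera adjusted p = 0.777), with CYP71A13 at -0.43 ± 0.30 and PAD3 at 0.42 ± 0.42. With the replicate-axis covariate 325 genes were called, 279 of them from the 3661, AIG2B (-0.62 ± 0.28) and GGCT2;2 (-1.08 ± 0.39) were not, and 2157 genes were called with thinned libraries. The count was 1758, 2285 and 1882 without aig2abc replicate 1, 2 or 3, and 1423, 1427 and 5503 without aig2abc pad4 replicate 1, 2 or 3.

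The last comparison set aig2abc pad4 against Col-0. Defensin, camalexin and detoxification genes stood above the wild type while PR1 did not differ past the test. PDF1.2A rose from 8.98 ± 3.53 to 3670 ± 846 CPM (SD, n = 3 each), a log2 change of 8.69 ± 0.45. PAD3 rose by 4.04 ± 0.47 and CYP71A13 by 4.83 ± 0.36. PR1 was at 0.50 ± 0.32 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.611), and PR2 was lower at -1.58 ± 0.34 (adjusted p = 0.0185), a call lost without Col-0 replicate 3 (log2 change -0.93, adjusted p = 0.121) and without aig2abc pad4 replicate 1 or 2. By this test 214 genes were higher and 49 lower. These numbers were 511 and 436 with the replicate-axis covariate, 296 and 142 with DESeq2, and 180 and 14 or 150 and 13 without aig2abc pad4 replicate 1 or 2.

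Defensin genes rose for 9 of 11, and for 10 adjusted over the list alone (camera adjusted p = 1e-69), with ORA59 up by 3.99 ± 0.30. Camalexin genes rose for 7 of 9, and for 8 adjusted over the list alone (camera adjusted p = 3.37e-33). Detoxification genes rose for 8 of 14, and for 11 adjusted over the list alone (camera adjusted p = 5.27e-21), such as GSTF2 by 2.17 ± 0.32. Indole glucosinolate genes rose for 8 of 22, and for 12 adjusted over the list alone (camera adjusted p = 2.43e-16), such as MYB51 by 2.33 ± 0.35. In senescence SAG12, SAG13 and SAG21 rose, SAG13 by 2.09 ± 0.32, with 7 of 8 adjusted over the list alone (camera adjusted p = 1.11e-10). SAG12 was at 3.45 ± 0.65, and at 5.63 without Col-0 replicate 1. In tryptophan synthesis ASB1, PAI2, IGPS and TSA1 rose, ASB1 by 1.76 ± 0.28, with 7 of 14 adjusted over the list alone (camera adjusted p = 1.75e-08). The PAI2 call was lost without Col-0 replicate 2 (edgeR adjusted p = 0.0774) or aig2abc pad4 replicate 2. These 6 calls also passed with an estimated correlation.

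A further 7 lists were called in this comparison and did not pass with an estimated correlation. The jasmonate genes CLH1 and JAZ1 were higher of 14, at 1.48 ± 0.29 and 1.52 ± 0.35, with 5 adjusted over the list alone (camera adjusted p = 0.000687; adjusted p = 0.0977 with an estimated correlation). The JAZ1 call was lost in 6 omissions, with edgeR adjusted p up to 0.134 without Col-0 replicate 1, and that of CLH1 without Col-0 replicate 3, at 0.0595. The immune gene NHL10 was higher at 2.91 ± 0.60, the only call of 21 and 1 adjusted over the list alone (camera adjusted p = 0.000814; adjusted p = 0.0936 with an estimated correlation), lost in 4 omissions with edgeR adjusted p up to 0.106 without aig2abc pad4 replicate 2. Heat shock had HSP70 higher of 4 and 2 adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.116 with an estimated correlation), its call at 1.55 ± 0.35 lost in 4 omissions with edgeR adjusted p up to 0.152 without Col-0 replicate 2, and its value at 2.15 without Col-0 replicate 3. The heat shock list was not called in 8 omissions, with camera adjusted p up to 0.292 without Col-0 replicate 1. Photosynthesis genes had a median of -0.41 with 0 of 26 called, and 0 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.172 with an estimated correlation). Aliphatic glucosinolate genes had a median of -0.53 with 0 of 25 called and 2 lower adjusted over the list alone (camera adjusted p = 0.000284; adjusted p = 0.0984 with an estimated correlation). KIN2 fell by 1.65 ± 0.28 and KIN1 by 1.97 ± 0.42 of the 12 abscisic acid and cold genes, with 3 lower adjusted over the list alone (camera adjusted p = 0.00135; adjusted p = 0.091 with an estimated correlation). The KIN1 call was lost without Col-0 replicate 3 or aig2abc pad4 replicate 2 (edgeR adjusted p up to 0.142). Of the AIG1 and AIG2 relatives AIG2A rose by 1.69 ± 0.22, and AIG2C and AIG2B fell by 6.81 ± 0.43 and 2.04 ± 0.45, with 1 and 2 of 10 adjusted over the list alone (camera adjusted p = 0.00842; adjusted p = 0.201 with an estimated correlation), a list not called without aig2abc pad4 replicate 1 (0.0602). The called members are the mutated genes themselves, so that list call follows in part from the genotype and says little about their relatives. The AIG2B call was lost in 4 omissions, with edgeR adjusted p up to 0.117 without aig2abc pad4 replicate 2, and its value was -2.88 without aig2abc pad4 replicate 3. Salicylic acid genes were not called (camera adjusted p = 0.461), nor were cysteine-rich receptor-like kinases (0.928) or folding genes (0.346), though without Col-0 replicate 3 salicylic acid and folding genes were (camera adjusted p = 0.0187 and 0.0388). The count of changed genes was 438 with DESeq2, 169 with these groups fitted alone, 947 with the replicate-axis covariate, 121 with thinned libraries and 163 without aig2abc pad4 replicate 2.

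Markers of other cell types were followed because whole shoots can differ in their tissue make-up. No cell-type list was called in any comparison by camera at an adjusted p, which lay between 0.371 and 0.936, though lists of 2 to 5 tested genes can show little. Of 3 myrosin cell markers TGG1 and TGG2, myrosinases that break down glucosinolates, fell by 3.60 ± 0.70 and 3.12 ± 0.59 in aig2abc against Col-0, and the transcription factor gene FAMA, which is also on the guard cell list, was at -0.09 ± 0.36 (camera adjusted p = 0.371). In aig2abc pad4 against aig2abc TGG1 and TGG2 rose by 3.40 ± 0.70 and 2.72 ± 0.59, with FAMA at -0.07 ± 0.36 (camera adjusted p = 0.371). Of 2 tested guard cell markers the potassium channel gene KAT1 was lower in aig2abc than in Col-0, at -2.90 ± 0.72 (camera adjusted p = 0.735). Of 5 phloem markers the sucrose transporter SUC2 was lower there, at -0.78 ± 0.29 (camera adjusted p = 0.735), and neither of the 2 tested shoot meristem markers was called (camera adjusted p = 0.735). The root list and the floral list had too few tested genes for the list test, and on the latter PI was higher in aig2abc than in Col-0, at 2.42 ± 0.52.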

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

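Every result here was marked because the aig2abc effect differed between plants with and without PAD4 by the interaction test in edgeR; the tests of thinned libraries, of the replicate axis, of plants without mutations and of mixed RNA were chosen only after the results were seen, the bounds for thinning before the counts they apply to were computed, while the splits were set in advance.

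The interaction was called for 2227 genes, with 429 without aig2abc pad4 replicate 2 and 4588 without aig2abc pad4 replicate 3 as the extremes over omissions. Among genes of defence it was positive for PR1 at 4.43, PR5 at 2.69, PR2 at 1.78, PAD3 at 3.34, PDF1.2A at 2.66, CYP79B3 at 2.14, CYP83B1 at 1.56 and LOX2 at 2.17 on the log2 scale. It was negative for ICS1 at -1.53 and VSP2 at -3.01. PAD3 had 2 counts over the pad4 libraries, so its fitted value rests on counts near the floor. Among the targeted genes AIG2A had 1.68 and AIG2B -2.28. The most negative of the others were CML11 at -4.29, Rap2.6L at -4.00, AT1G25570 at -3.77, GGCT2;2 at -3.71, and AT3G26445 and BIR1 at -3.70. Positive values of AT5G41920 at 9.27, AT1G68730 at 9.20, AT3G62450 at 8.62, AT4G33890 at 8.35 and AT1G20030 at 7.79 belong to genes with 0 counts in aig2abc, so these fitted values are no bounds. AT3G01345 at 7.95 was nearly silent in every group but Col-0, at 101 ± 15.9 CPM (SD, n = 3) there and 1.52 CPM or less elsewhere. The lists called were defensins (camera adjusted p = 0.00147; adjusted p = 0.16 with an estimated correlation), salicylic acid (0.0203; adjusted p = 0.464 with an estimated correlation) and photosynthesis (0.0262; adjusted p = 0.413 with an estimated correlation). The salicylic acid list was not called without Col-0 replicate 3 (camera adjusted p = 0.134), nor photosynthesis without Col-0 replicate 2 (0.101), pad4 replicate 1 (0.0575) or 3 (0.0639), or aig2abc pad4 replicate 3 (0.085).

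In leave-one-out fits the calls of PR1, PR5, PDF1.2A, AIG2A, GGCT2;2, AT1G25570, AT3G26445, AT1G68730, AT3G01345 and AT3G62450 passed in every omission. PR5 was at 2.06 without Col-0 replicate 3 and GGCT2;2 at -4.75, BIR1 at -4.89, CML11 at -5.76 and AIG2B at -3.11 without aig2abc pad4 replicate 3. Without pad4 replicate 3 BIR1 was at -3.04 and PAD3, then without counts in pad4, at 5.62, and without pad4 replicate 1 AT1G68730 was at 9.98 and AT3G62450 at 9.27. AT3G01345 was at 9.13 without pad4 replicate 1, 8.87 without aig2abc replicate 2 and 7.28 without aig2abc pad4 replicate 3. Without Col-0 replicate 1 AT5G41920 was at 8.43, AT4G33890 at 7.43 and AT1G20030 at 6.74. Rap2.6L was at -4.59 and VSP2 at -3.81 without Col-0 replicate 2, and Rap2.6L at -3.31 and PR2 at 1.13 without Col-0 replicate 3. The other single genes lost the call in at least 1 omission. For CML11 and Rap2.6L that was pad4 replicate 3 (edgeR adjusted p = 0.0521 and 0.0542), and for AT5G41920 aig2abc replicate 3 (0.052). The highest edgeR adjusted p was 0.142 for ICS1 without aig2abc pad4 replicate 1, 0.0865 for CYP79B3, 0.0549 for CYP83B1 and 0.0762 for VSP2 without that library. It was 0.0687 for PAD3 and 0.0775 for AIG2B without aig2abc pad4 replicate 2, 0.0695 for LOX2 and 0.0738 for PR2 without pad4 replicate 3, and 0.0536 for BIR1 without aig2abc pad4 replicate 2. Of the genes without counts, AT1G20030 reached 0.0744 and AT4G33890 0.0591 without aig2abc replicate 3.

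The breadth of the response was the pattern weighed first: 5656 genes were called in aig2abc against Col-0 and 603 in aig2abc pad4 against pad4, a ratio of 9.38 (3730 without aig2abc replicate 1; 381 without pad4 or aig2abc pad4 replicate 2, 935 without aig2abc pad4 replicate 3). With every library thinned to the smallest total the ratio was 13.9 to 15.2 in 5 thinnings, above the bound of 1.5 set before these counts were computed. The difference thus remained at equal depth, so at 584342 counts it does not rest on unequal totals alone. Thinning takes most from the deeper libraries and lowers the power, with 2769 and 192 genes called in the first thinning. That the ratio rose above 9.38 therefore decides nothing about the part of depth at full totals. With only the aig2abc pad4 libraries thinned to the aig2abc totals 450 to 587 genes were called against pad4 in 5 thinnings, which argues against a shallow group raising the count. With the replicate axis as covariate the ratio was 0.802 and 3.46% of the genes with an interaction stayed called, yet scores exchanged at random within groups gave ratios of 0.351 to 8.08 in 20 exchanges, 10 of them at 1.5 or below, and kept 0 to 90.6% of the interaction; the median absolute log2 change of the 5656 genes went with the axis, at 0.816 with the real scores and 0.877 to 2 in the exchanges, but a mutation effect that runs along the axis would give this too, so the axis cannot be told apart from a mutation effect. Of the 11 lists called up in aig2abc at the preset correlation 10 stayed up with the covariate. Only 4 of the 11 passed with an estimated correlation, and these 4 (defensins, camalexin, detoxification and tryptophan synthesis) passed with both (camera adjusted p = 0.000869, 0.00552, 0.00351 and 0.0102). That argues against a straight-line effect of the axis as the whole cause of the rise of these 4. The aig2abc scores, at -60.8 or lower, lie outside those of the other libraries, at -39.4 or higher, so the covariate extrapolates its slope to them. The leading axis within aig2abc hardly correlated with those within the other groups (rank correlation over genes 0.03 to 0.08). That axis includes aig2abc replicate 2, with only 584342 counts. The axes within Col-0, pad4 and aig2abc pad4 correlated with the aig2abc minus Col-0 difference, at -0.52, -0.57 and -0.62. With the aig2abc pad4 minus pad4 difference the values were 0.02, 0 and 0.1. The first difference thus ran in part along axes seen within pad4 and aig2abc pad4, which share no library with it. A mutation effect that runs along the axis, and a difference in growth, RNA or handling of the aig2abc plants that the labels do not name, stay open, since depth and axis score both go with the genotype.

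AIG2B was lower in aig2abc pad4 than in pad4 and not called in aig2abc against Col-0. Plants without the mutations in the aig2abc libraries are argued against by AIG2C, whose highest level there was 5.61% of the lowest Col-0 level. With the covariate AIG2B was at -1.84 in aig2abc against Col-0, while exchanged scores gave -1.76 to 1.02, 1 of 20 of them called lower, so the axis may hide a fall and stays open. Reads shared between AIG2A, AIG2B and AIG2C, and a difference in the alleles between the genotypes, were not tested.

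PR1 was higher in aig2abc pad4 than in pad4. Mixed-in RNA of aig2abc plants would carry PAD4 along, but PAD4 went at most 10.9% of the way from the pad4 to the aig2abc level in any aig2abc pad4 library (mean 7.15 ± 3.34%, SD, n = 3), against 67.6 ± 22.7% for PR1. All 3 pad4 libraries lay within the range of aig2abc pad4 on the replicate axis, yet the highest PR1 level among them was 4.08% of the lowest in aig2abc pad4, which argues against the axis as the cause. A response of PR1 to loss of the AIG2 genes that needs little PAD4 is a hypothesis consistent with these values, found and tested on the same data.

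Other splits of the libraries bear on how far chance can be excluded. For the interaction, 2 of 100 splits, the real one among them, gave as many genes as the real 2227, the highest other at 4168. These splits exchanged all 12 libraries over the 4 groups, so the separate effects of aig2abc and pad4 were broken up as well. The share, under 0.05, therefore bears on genotype effects of any kind and cannot exclude chance for the interaction alone. The comparisons of 6 libraries have 10 splits each, too few for a share under 0.05. The real count and the highest other were 5656 and 0 for aig2abc against Col-0, 3661 and 0 for aig2abc pad4 against aig2abc, and 104 and 0 for pad4 against Col-0, where only the real split, 1 of 10, gave as many. For aig2abc pad4 against pad4, 2 of 10 did, with 603 and 1010, and for aig2abc pad4 against Col-0, 2 of 10, with 263 and 345. The split with 1010 parts pad4 replicate 1 and aig2abc pad4 replicates 1 and 2 from the rest, and that with 345 parts Col-0 replicate 1 and the same pair, which points to a structure of the samples that follows the axis scores.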

How the results depend on the processing

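The covariate, the thinned sets and the joint omission of Col-0 replicate 1 and aig2abc pad4 replicate 3 were tests chosen only after the results were seen. Of the 374 named-gene and 96 list results no call changed direction under any alternative run, and other genes were not followed. Over 7339 refits of 374 named-gene results under settings fixed in advance, 6885 kept their side of the threshold, 416 lost the call and 38 gained it, and of 1728 for the lists 1613, 88 and 27. Many of these genes were named for small p or large changes in the same data, so a high share kept is partly built in. Over all alternatives 317 of 1553 refits of named genes in the interaction lost the call. The counts of changed genes below are those that moved by over 1.5 times, and the cause was not tested. DESeq2 called 158 genes in pad4 against Col-0 and 438 in aig2abc pad4 against Col-0. Fitted alone, the latter gave 169, and the overlap of aig2abc effects 251. With an estimated correlation 23 of 96 list tests were called, and 24 with the covariate as well, against 58 with the preset. With the covariate the counts were 1377 for aig2abc against Col-0, 1717 for aig2abc pad4 against pad4, 86 for the interaction, 325 for aig2abc pad4 against aig2abc, and 240 and 947 for pad4 and aig2abc pad4 against Col-0. With all libraries thinned they were 2769, 192, 1230, 2157, 29 and 121 in that order, with an overlap of 120, where fewer counts by construction lower the power. Without aig2abc replicate 2 and with the rest thinned to aig2abc replicate 1, the interaction had 1014. Without Col-0 replicate 1 and aig2abc pad4 replicate 3 the counts were 1498 for aig2abc pad4 against pad4, 3979 for the interaction, 6294 for aig2abc pad4 against aig2abc, and 157 and 545 for pad4 and aig2abc pad4 against Col-0. Over the omissions of each library the counts ranged from 3730 to 6210 for aig2abc against Col-0, 381 to 935 for aig2abc pad4 against pad4, 429 to 4588 for the interaction, 1423 to 5503 for aig2abc pad4 against aig2abc, 67 to 132 for pad4 against Col-0 and 163 to 326 for aig2abc pad4 against Col-0. The highest counts came without aig2abc pad4 replicate 3. The overlap ranged from 263 to 395 and the list tests from 51 to 59. Replicate numbers paired the samples only in part. Deviations of the 15 same-numbered pairs correlated at -0.27 to 0.55, over 0.1 in 5 of them, and the own number was the best match in 15 of 30 tries. Each try chose among few libraries and each pair was tried from both sides, so many matches can arise by chance, and that share was not computed. The replicate 1 libraries of Col-0, pad4 and aig2abc pad4 deviated together, at 0.52, 0.54 and 0.55. They also had the highest replicate-axis scores of their groups, at 84, 52.9 and 57.6. Pairs with an aig2abc library lay between -0.15 and 0.05. With the replicate block the counts were 6003, 519, 2664, 4349, 71 and 393 in the same order, the overlap 358 and the called lists 55. Without a number, pad4 replicate 3 formed a block of its own and added nothing to the pad4 mean. Counts that involve pad4 therefore mix the block with the loss of that library. The low depth of aig2abc replicate 2 limits what can be seen of weakly expressed genes there.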

Other observations

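The gene families below, 15 with 90 tests, were chosen only after the results were seen, and so were their tests. Some members are also on the lists above, such as WRKY33 on the camalexin list and the chitinase PR3 on the defensin list. The family results are therefore not independent of the list results. Among genes annotated as peroxidases, 9 of 24 rose in aig2abc pad4 against pad4 (camera adjusted p = 8.55e-21; adjusted p = 0.0199 with an estimated correlation), with PRXCA up by 3.44 ± 0.32 on the log2 scale (SE; n = 3 libraries a group). WRKY transcription factors rose for 11 of 32 (camera adjusted p = 7.44e-12; adjusted p = 0.0298 with an estimated correlation), with WRKY45 up by 4.51 ± 0.35 and WRKY33, a regulator of camalexin genes, by 2.13 ± 0.33. Chitinases, which attack fungal cell walls, rose for 5 of 13 (camera adjusted p = 1.04e-07; adjusted p = 0.0311 with an estimated correlation), with AT2G43590 up by 7.72 ± 0.41. None of the 3 families passed with an estimated correlation in aig2abc against Col-0. There peroxidases rose for 12 of 24 and fell for 1 (camera adjusted p = 2.4e-08; adjusted p = 0.0696 with an estimated correlation), WRKY factors rose for 16 of 32 and fell for 2 (camera adjusted p = 2.41e-06; adjusted p = 0.113 with an estimated correlation), and chitinases rose for 6 of 13 (camera adjusted p = 0.000585; adjusted p = 0.0885 with an estimated correlation).

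In aig2abc against Col-0, SAUR genes, which respond to auxin, fell for 18 of 34 and rose for 2 (camera adjusted p = 3.98e-05; adjusted p = 0.482 with an estimated correlation), with SAUR20 down by 3.85 ± 0.48 on the log2 scale. Expansins, which loosen cell walls, fell for 10 of 16 and rose for 2 (camera adjusted p = 0.00863; adjusted p = 0.489 with an estimated correlation). The medians of these families were -2.26 and -1.46, and -2.35 and -1.54 with RLE size factors. In aig2abc pad4 against pad4 SAUR genes fell for 3 and rose for 1, and expansins fell for 1 (camera adjusted p = 0.00863 for each; adjusted p = 0.558 and 0.489 with an estimated correlation).

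A set of 4 genes was lower in all 3 mutant groups than in Col-0 by edgeR, and 0 genes were higher in all 3; the groups share the Col-0 libraries, so such counts lie above chance with no effect at all. AT3G01345 stood at 101 ± 15.9 CPM in Col-0 (SD, n = 3) and at 1.52, 0.268 and 0.544 CPM in aig2abc, pad4 and aig2abc pad4. AT3G42658.1 stood at 66.1 ± 24.1 CPM and at 1.29, 7.98 and 2.07 CPM, and QQS at 21.1 ± 2.87 CPM and at 2.95, 7.54 and 3.69 CPM. AT2G05914 stood at 8.04 ± 4.8 CPM and at 1.68, 0.335 and 0.635 CPM. No explanation was tested for these genes.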
